A study of Homo sapiens with 6 samples.

How the data were processed

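RNA was measured by sequencing in 6 libraries of A673 cells, an Ewing sarcoma line, taken 72 h after transfection with esiRNA (pools of short interfering RNA made by enzymatic digestion of long double-stranded RNA). The groups were esiGFP (control), esiFLI1 and esiUSP9X, with 2 libraries each. Per the labels' protocols, ribosomal RNA was depleted from 2 µg of total RNA, stranded libraries were prepared, and 75-nt single-end reads were taken on a NextSeq500. The submitters' processing notes name TopHat, Cufflinks and Cuffdiff and the builds hg19 and GRCh37, without versions, parameters or roles. The deposited table holds FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) made by the authors, with a value per gene symbol and library. No further scaling between libraries is stated. The annotation, and whether counting used the strand, are not given in the sources used here, so overlapping genes and near-identical copies are uncertain.

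The table listed 25268 gene symbols. A stray last line was dropped (1 line), and 0 columns belonged to no sample. Genes with at least 1 FPKM in at least 2 of the 6 libraries were kept, which left 12169. Of these, 107 were listed at 0 in at least 1 library. No read counts were used here, so the depth of each library is unknown, and no counting intervals or detection limits were computed. Values under 0.05 FPKM were searched for steps that single reads would leave, in bins of 0.01, and the fullest bin held at most 4.09% of them, so no depth was inferred. Transcript length and GC content came from GENCODE v29, which is on another build, so no coordinates were used. A transcript was found for 22597 of the 25268 symbols (89.4%).

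Log2(FPKM + 1) values were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with all 6 libraries and the 3 group means in a single fit. Tests were two-sided, with Benjamini-Hochberg adjustment over the kept genes, and a gene was called at an adjusted p under 0.05. Fold changes on this scale understate the change of genes with low FPKM. Standard errors come from this model, and SD values are over the 2 libraries of a group. The fit without a block had 3 residual degrees of freedom and 2.21 prior ones. The comparisons were esiFLI1 with esiGFP, esiUSP9X with esiGFP, and esiUSP9X with esiFLI1, the last of which tests the difference of the effects. The labels do not state that replicates came from separate cultures, so all p-values measure only the spread between these samples.

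The labels give each group replicates 1 and 2 but state no shared day. Deviations from the group mean were therefore compared between groups across genes, before calls were counted. Their correlation was 0.647 for esiGFP and esiFLI1, 0.589 for esiGFP and esiUSP9X, and 0.644 for esiFLI1 and esiUSP9X. Each value was over 0.1, so the pairing by number was taken from the data, not from the design. A second fit added the replicate number as a block, with 2 residual degrees of freedom and 5.72 prior ones. Values called blocked come from that fit, and they stand beside a result where they change its call or move a count by over 1.5 times.

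Before the data were examined, 26 gene lists with 721 genes were fixed, along with the tests, the alternatives and the rule for naming genes. Lists with at least 3 kept genes were tested with camera in limma, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison, and again with an estimated correlation. With an estimated correlation camera also tests on the residual degrees of freedom, 3 without a block and 2 with it. That alone raises its p-values. Counts adjusted over the list alone use the gene tests of the fit without a block, unless the blocked fit is named, adjusted only among that list's genes. The rule names the targets, FLI1, EWSR1 and USP9X. It adds up to 10 called genes per direction and comparison whose libraries do not overlap. For each list described, it takes the 4 members with the smallest adjusted p, or the 2 with the highest mean FPKM if none is called. It also takes up to 5 shared calls per direction. Small and uncharacterised RNA symbols and Y-linked genes were excluded. Genes named only from the blocked fit, SNORD35A, and the members of 4 gene families were chosen after their values were seen. Some of the genes and 1 of the families are not reported here.

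Overlaps and correlations between the knockdowns were set beside 100 simulations of unchanged groups against the same controls, and beside the overlap of independent lists. The whole procedure was tested on simulated data made from the 12062 kept genes above 0 in all libraries, with 200 genes changed by known folds. The replicate effect and spread of these data were taken from the blocked fit, so that fit was the right model by construction. In the esiFLI1 comparison the blocked fit recovered 88.4% of genes changed 1.5-fold and 99.8% of those changed 2-fold, with 7.47% false calls. In the esiUSP9X comparison these values were 90.2%, 99.5% and 8.04%. The fit without a block recovered 0% of the changed genes in either comparison at every fold tried (1.5, 2, 3 and 4), so a gene it does not call is not shown to be unchanged. In the real data that fit did call genes, 342 in esiFLI1, so these shares hold for the simulated setting only.

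Alternatives fixed in advance were other pseudocounts (0.1 and 0.5), no filter, a filter of 5 FPKM, median scaling, quantile normalization, eBayes without a trend, robust eBayes, small RNA symbols left out, only the 2 groups compared, the replicate block, each library left out in turn, stricter thresholds (adjusted p under 0.01, or a log2 change of at least 1), and each knockdown against a different control library. Genes listed at 0 left out, a correction for transcript GC content (a spline with 5 degrees of freedom per library), combinations of these or of median scaling or left-out libraries with the block, and single libraries of each knockdown against the control of their own, different replicate numbers were added after the data were seen. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used for sequence properties and plots. Blood cell markers were not tested, because 1 of the 15 listed genes was kept.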

Results

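RNA levels were measured in A673 cells, an Ewing sarcoma line that carries the EWSR1-FLI1 fusion gene, 72 h after transfection. The fusion encodes EWS-FLI1, a transcription factor that joins part of EWSR1 to the DNA-binding part of FLI1. Cells received esiRNA against GFP as the control, against FLI1, or against USP9X, a deubiquitinase that removes ubiquitin from other proteins. Each group had 2 libraries. The FPKM of a library summed to between 781732 and 907926, and between 11310 and 12071 genes reached at least 1 FPKM. A symbol for a microRNA, MIR6723, held between 33.2% and 50.9% of the sum, and whether its fragments come from the microRNA was not analysed here. The read depth is unknown, so a low or 0 value cannot be read as absence.

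Each esiRNA lowered its own target, and USP9X loss left FLI1 RNA near the control level. FLI1 RNA, which includes the 3' part of the fusion, was 24.1 and 36.4 FPKM in the esiGFP libraries (30.3 ± 8.70, SD, n = 2), 12.7 and 14.1 in esiFLI1 (13.4 ± 1.03) and 25.0 and 31.9 in esiUSP9X (28.4 ± 4.88). USP9X RNA was 20.6 and 26.5 FPKM in esiGFP (23.6 ± 4.21, SD, n = 2), 26.2 and 37.7 in esiFLI1 (32.0 ± 8.13), and 5.31 and 7.10 in esiUSP9X (6.21 ± 1.26). FLI1 fell in esiFLI1 by 1.09 on the log2 scale in the blocked fit (SE 0.12, adjusted p = 4.4e-04), while the fit without a block did not call it (SE 0.27, adjusted p = 0.13). USP9X fell in esiUSP9X by 1.77 in limma's blocked fit (SE 0.10, adjusted p = 4.5e-04), again without a call in limma's other fit (SE 0.28, unadjusted 0.0012, adjusted p = 1). Both replicates of each knockdown showed the fall, with log2 differences of -0.88 and -1.31 for FLI1 and -1.77 and -1.77 for USP9X.

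The series asks whether USP9X keeps the fusion protein stable. RNA can show whether the fusion's transcript or its target genes moved, but not the level of the protein. In esiUSP9X, the log2 change of FLI1 was -0.07 (SE 0.27, adjusted p = 1), with 0.05 and -0.19 in the replicates and a blocked 95% interval of -0.35 to 0.21. EWSR1 RNA, which includes the 5' part of the fusion, was 111 ± 8.39 FPKM in esiGFP (SD, n = 2), 89.5 ± 6.48 in esiFLI1 and 110 ± 3.76 in esiUSP9X. Its log2 change in esiUSP9X was -0.01 (SE 0.17, adjusted p = 1). In esiFLI1, EWSR1 fell by 0.31 in the blocked fit (adjusted p = 0.048; 0.48 without a block), a call that ended without esiGFP 2 (0.38), esiFLI1 2 (0.27), esiUSP9X 1 (0.080) or esiUSP9X 2 (0.083), with 0.023 to 0.78 over all alternatives. USP9X rose by 0.41 in esiFLI1 in the blocked fit (adjusted p = 0.013; 0.60 without a block), a call that ended without esiGFP 2 (0.12) or esiFLI1 2 (0.082), with 0.0061 to 0.88 over all alternatives.

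**Figure D1:**
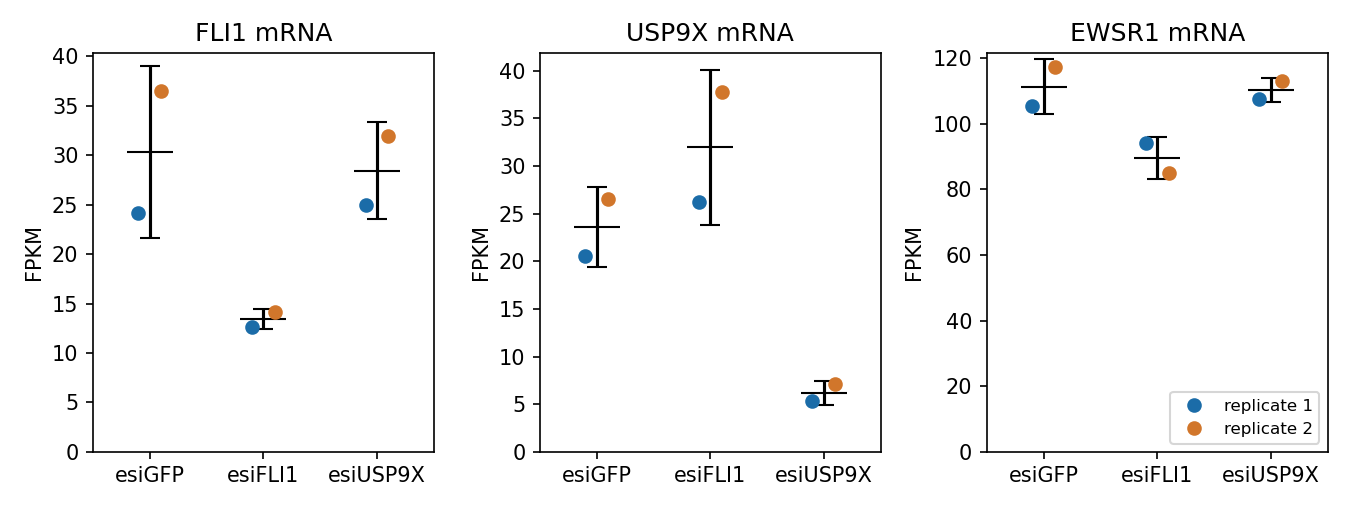
FPKM (y axis, linear) of FLI1, USP9X and EWSR1 in each library, by group, with points for replicates and bars for the mean and SD of 2 libraries. FLI1 was lowest in esiFLI1 (12.7 and 14.1 FPKM) and USP9X was lowest in esiUSP9X (5.31 and 7.10 FPKM).

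The comparison of esiFLI1 with esiGFP asks which genes depend on the fusion. DKK1, a secreted Wnt inhibitor, went from 3.31 to 400 FPKM (log2 change 6.56, SE 0.32, adjusted p = 0.0058). IGFBP5, which binds insulin-like growth factors, went from 1.38 to 138 FPKM (5.87, SE 0.29, adjusted p = 0.0058). POSTN, a matrix protein, went from 8.17 to 366 FPKM (5.46, SE 0.62, adjusted p = 0.022). LOX, which crosslinks collagen, rose by 4.42, MGP, a calcification inhibitor, by 4.35, and TGFB2, a growth factor, by 4.27, all with an adjusted p of at most 0.0077. CRYAB, a small heat shock protein, rose by 4.13, SPRY1, a feedback inhibitor of receptor tyrosine kinase signalling, by 4.05, and L1CAM, a cell adhesion molecule, by 4.03 (largest adjusted p of the 3, 0.012). EEF1A1, a translation elongation factor, was listed at 0 in both esiGFP libraries and at 2928 and 3160 FPKM in esiFLI1, so no fold is given.

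ETV4 and ETV5, transcription factors of the ETS family, fell in esiFLI1 by 2.24 (SE 0.28, 12.2 to 1.83 FPKM, adjusted p = 0.027) and by 1.49 (SE 0.21, adjusted p = 0.035). ASNS, the enzyme that makes asparagine, fell by 1.99 (SE 0.19, 128 to 31.3 FPKM, adjusted p = 0.014), and PSAT1, an enzyme of serine synthesis, fell by 1.54 (SE 0.15, 216 to 73.8 FPKM, adjusted p = 0.015). DDIT3, a stress-induced transcription factor, fell by 1.41 (adjusted p = 0.024). The other falls among the 10 largest were C7, a complement component (-1.95), CLDN1, a tight junction protein (-1.76), the transcription factors FEZF1 (-1.74) and SOX1 (-1.56), and the peptide hormone CCK (-1.65), with adjusted p between 0.016 and 0.033. The blocked fit added ATF5 (-2.36), VMO1 (-2.32), TRIB3, a stress-induced pseudokinase (-2.21), NR0B1, a nuclear receptor (-2.09), PPP1R1A, a phosphatase inhibitor (-1.97), and SLC7A5, an amino acid transporter (-1.79), each with a blocked adjusted p of at most 4.9e-05. RPL21P28, a ribosomal protein pseudogene whose value is uncertain, was 242 and 13.3 FPKM in esiGFP and 0.0302 and 0.985 in esiFLI1 (blocked adjusted p = 0.0039).

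In limma's fit without a block, 314 genes were higher and 28 lower in esiFLI1, of 12169 tested, and 1923 had an unadjusted p under 0.05. The blocked fit called 2502 higher and 2623 lower, which included all 342 genes called without a block, in the same direction. The share of calls that were higher was 91.8% without a block and 48.8% with it, and 52.4% after a correction for transcript GC content. Of the 342 calls, 296 higher and 28 lower genes differed by at least 2-fold, and with the block 633 and 192 did. The count without a block was 6 without esiGFP 1, 2 without esiGFP 2, 1 without esiFLI1 1, 1 without esiFLI1 2, 64 without esiUSP9X 1 and 69 without esiUSP9X 2. Each of these left EEF1A1 called. The blocked count stayed between 2606 (without esiFLI1 2) and 4771 (without esiUSP9X 1), and was 3466 without esiGFP 2.

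Genes known to be activated by EWS-FLI1 fell as a group in esiFLI1, and genes known to be repressed by it rose. Of 37 kept activated targets, 0 rose and 6 fell (0 and 18 adjusted over the list alone, 2 and 28 blocked), with a median log2 change of -0.82 (camera adjusted p = 6.1e-13; adjusted p = 0.074 with an estimated correlation). Among them were CCND1, a cyclin of the G1 phase (-1.13), STEAP1, a membrane protein (-1.28), NPY1R, a neuropeptide Y receptor (-1.33), and CCK. NKX2-2, a homeobox factor, fell in the blocked fit (-1.40, adjusted p = 8.3e-05). Of 19 kept repressed targets, 12 rose and 0 fell (13 and 0 adjusted over the list alone, 14 and 1 blocked), with a median of 1.84 (camera adjusted p = 9.2e-14; adjusted p = 0.074 with an estimated correlation). They included DKK1, SPRY1, the hyaluronan receptor CD44 (2.26) and NT5E, a surface enzyme that makes adenosine (3.50).

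Groups tied to matrix, adhesion and cell shape rose in esiFLI1. Of 29 extracellular matrix genes, 12 rose and 0 fell (21 and 0 adjusted over the list alone, 25 and 0 blocked), with a median of 1.64 (camera adjusted p = 9.3e-17; adjusted p = 0.14 with an estimated correlation). COL6A3 rose by 2.62, FBN1, a microfibril protein, by 3.14, SPARC, a collagen-binding protein, by 2.26, and MMP2, a matrix protease, by 3.05. Of 24 YAP and TEAD target genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone, 18 and 2 blocked; median 0.53, camera adjusted p = 1.2e-09; adjusted p = 0.14 with an estimated correlation), among them ANKRD1 (3.99), MYOF (2.38) and CYR61 (1.95). Of 31 actin and focal adhesion genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone, 18 and 3 blocked; median 0.39, camera adjusted p = 1.7e-04; adjusted p = 0.43 with an estimated correlation). These were tropomyosin TPM1 (2.60), the myosin light chain MYL9 (1.77), the integrin ITGA3 (2.25) and vinculin, VCL (1.21). Of 19 TGF-beta response genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone, 8 and 2 blocked; median 0.25, camera adjusted p = 0.0032; adjusted p = 0.45 with an estimated correlation). Among them were TGFBR2 (1.84), LTBP1 (1.25) and TGFBI (2.17), and the list's call ended without esiGFP 2 (0.065) or esiFLI1 1 (0.13), with adjusted p from 3.6e-04 to 0.45 over all alternatives.

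Interferon response genes and histone genes were also higher in esiFLI1 as lists, though no member was called by limma without a block (0 genes). Of 27 interferon response genes, 10 rose and 0 fell adjusted over the list alone and 18 rose and 1 fell in the blocked fit (median 0.60, camera adjusted p = 1.5e-05; adjusted p = 0.17 with an estimated correlation). In the blocked fit the transcription factor IRF1 rose by 1.27, IFITM1 by 1.25 and IFITM3 by 0.60, antiviral membrane proteins, the immunoproteasome subunit PSMB9 by 1.15 and STAT2 by 0.94. Of 11 replication-dependent histone genes, 2 rose adjusted over the list alone and 6 in the blocked fit (median 0.41, camera adjusted p = 0.013; adjusted p = 0.50 with an estimated correlation). HIST1H2BC (0.95), HIST1H2BD (0.91) and HIST1H2BK (0.36) rose in the blocked fit, with adjusted p of at most 0.021. The histone list's call ended without esiGFP 2 (0.075) or esiFLI1 1 (0.11), with no filter on low values (0.36), and, blocked, without esiGFP 1 (0.18), with 8.8e-04 to 0.50 over all alternatives. Histone and IFITM genes have near-identical copies, so single values are uncertain.

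Lists for DNA replication, protein turnover and translation fell in esiFLI1 by small median amounts, again with 0 members called by limma without a block. Of 35 S phase genes, 1 rose and 27 fell in the blocked fit (median -0.44, camera adjusted p = 8.8e-07; adjusted p = 0.14 with an estimated correlation). The polymerase clamp PCNA fell by 0.50, the helicase subunit MCM7 by 0.51, E2F1 by 0.82 and the licensing factor CDT1 by 0.96 in that fit. Of 31 proteasome subunits, 21 fell in the blocked fit (median -0.38, camera adjusted p = 1.5e-06; adjusted p = 0.14 with an estimated correlation), among them PSMA7 (-0.45), PSMB1 (-0.37), PSMD12 (-0.85) and PSMD14 (-0.65). Of 54 cytosolic ribosomal protein genes, 24 fell in the blocked fit (median -0.32, camera adjusted p = 7.4e-06; adjusted p = 0.44 with an estimated correlation), such as RPLP1 (-0.65) and RPS7 (-0.61). RPL7 (-0.15) and RPS27 (-0.21) were called in neither fit and became 0 and 0.081 under quantile normalization, which also ended the list's call (adjusted p = 0.16, with 5.5e-08 to 0.44 over all alternatives). Ribosomal protein genes share reads with their pseudogenes and are uncertain. Without a block, none of these 3 lists had a member called when adjusted over the list alone (0 genes each).

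Lists for energy and lipid metabolism also fell in esiFLI1. Of 32 nuclear respiratory chain genes, 18 fell in the blocked fit and 0 without a block or adjusted over the list alone (median -0.31, camera adjusted p = 1.2e-04; adjusted p = 0.44 with an estimated correlation). ATP5B (-0.65), COX7C (-0.53), SDHB (-0.83) and CYC1 (-0.87), subunits of the respiratory complexes, fell in the blocked fit. Of 22 hypoxia and glycolysis genes, 1 rose and 1 fell (1 and 6 adjusted over the list alone, 3 and 16 blocked; median -0.48, camera adjusted p = 0.0010; adjusted p = 0.44 with an estimated correlation). Hexokinase HK2 fell by 1.30 and adrenomedullin, ADM, rose by 2.99, while VEGFA (-1.08) and the glycolytic enzyme PGK1 (-0.84) fell in the blocked fit. Of 28 stress and unfolded protein response genes, 0 rose and 3 fell (0 and 4 adjusted over the list alone, 5 and 12 blocked; median -0.12, camera adjusted p = 0.011; adjusted p = 0.43 with an estimated correlation). The 3 were ASNS, PSAT1 and DDIT3, and ATF4, the transcription factor upstream of many of these genes, fell in the blocked fit (-0.79, adjusted p = 7.7e-04). Of 24 cholesterol synthesis genes, 8 fell in the blocked fit and 0 without a block or adjusted over the list alone (median -0.24, camera adjusted p = 0.027; adjusted p = 0.44 with an estimated correlation). HSD17B7 was among the 8 (-0.79), while FDPS (-0.13) and IDI1 (-0.12) were called in neither fit and turned positive under quantile normalization. The cholesterol call ended without esiGFP 1 (0.32; blocked 0.26) or esiFLI1 2 (0.13), under quantile normalization (0.30) and with a filter of 5 FPKM (0.072), with 0.0038 to 0.44 over all alternatives. The stress call ended with a correction for GC content (0.063), with a filter of 5 FPKM (0.051) and, blocked, without esiFLI1 1 (0.053), with 0.0013 to 0.43 over all alternatives.

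In all, 15 of the 25 lists tested were called in esiFLI1 with or without a block, and 0 with an estimated correlation in either fit. The other 10 were not called by camera, and their counts without a block were as follows, with blocked counts after them. ETS family transcription factors had 0 rises and 2 falls among 15 (1 and 4 adjusted over the list alone, 3 and 5 blocked; adjusted p = 0.21), with a median of 0.04 against a mean of -0.31 and a downward test. Immediate early and MAPK feedback genes had 2 and 2 among 23 (3 and 5 adjusted over the list alone, 7 and 10 blocked; median -0.28, adjusted p = 0.41). Wnt response genes had 3 and 1 among 13 (4 and 4 adjusted over the list alone, 5 and 4 blocked; adjusted p = 0.73), with a median of -0.13 against a mean of 0.60 and an upward test, and camera called them with the block without esiGFP 1 (0.0068) or esiGFP 2 (0.0093), where 0.97 was the highest value over all alternatives. Neural and neuroendocrine genes had 2 and 2 among 16 (5 and 2 adjusted over the list alone, 6 and 8 blocked; median -0.34, adjusted p = 0.73), and p53 target genes 1 and 0 among 24 (1 and 1 adjusted over the list alone, 4 and 7 blocked; median -0.07, adjusted p = 0.83). Among 43 deubiquitinases (median -0.09, adjusted p = 0.64), 22 apoptosis regulators and 34 G2 and mitosis genes, limma called 0 without a block, and adjusted over the list alone it called 0, 2 higher and 0. In the blocked fit 2 deubiquitinases rose and 7 fell, 7 apoptosis regulators rose and 3 fell, and 4 G2 and mitosis genes rose and 4 fell. Apoptosis regulators had a median of -0.10 against a mean of 0.10 and an upward test (adjusted p = 0.72). G2 and mitosis genes had a median of -0.01 against a mean of 0.01 and a downward test (adjusted p = 0.73). Few markers of other cell types were kept, with 3 of 12 endothelial (1 higher, 1 adjusted over the list alone, 2 higher and 1 lower blocked; median 0.82, adjusted p = 0.12) and 3 of 15 epithelial (0 called, 0 adjusted over the list alone, 1 higher blocked; median 0.12, adjusted p = 0.37).

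**Figure D2:**
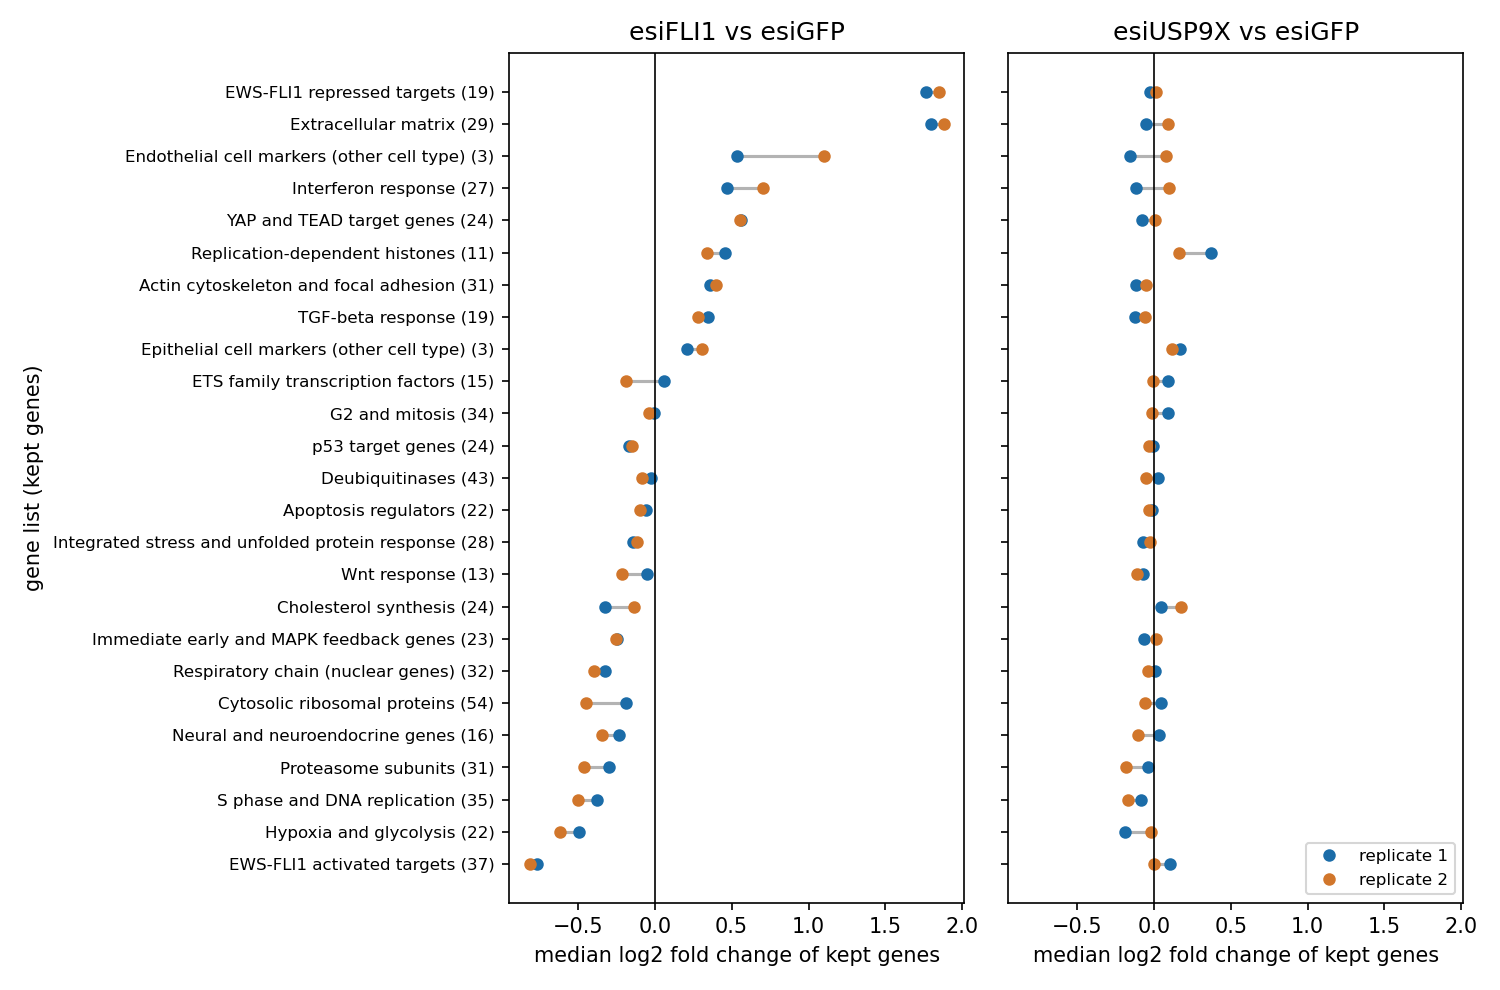
Median log2 fold change of the kept genes of each of the 25 lists tested (x axis), as points for replicate 1 and replicate 2, for esiFLI1 (left) and esiUSP9X (right) against esiGFP. Extracellular matrix genes had the median 1.64 in esiFLI1, and the activated targets -0.82 there against 0.05 in esiUSP9X.

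The comparison of esiUSP9X with esiGFP asks what follows the loss of USP9X. Few genes were called, with EEF1A1 and FN1, the gene of fibronectin, called in both fits. EEF1A1 was listed at 0 in both esiGFP libraries and at 3197 and 3578 FPKM in esiUSP9X, and FN1 was listed at 0 in all esiGFP and esiFLI1 libraries and at 890 and 900 FPKM in esiUSP9X. A listed 0 cannot be read as absence, so neither gene is read as a rise. In the blocked fit TXNIP, an inhibitor of thioredoxin and of glucose uptake, rose by 1.20 (SE 0.11, 6.21 to 15.5 FPKM, adjusted p = 0.0087). LCP1, an actin-bundling protein, rose by 1.09, KRT8, a keratin, by 0.86, RPN1, a subunit of the oligosaccharyltransferase, by 0.84, and the read-through ABHD14A-ACY1 by 1.10, with adjusted p between 0.012 and 0.022. In that fit NQO1, a quinone reductase, fell by 1.05 (33.4 to 15.6 FPKM, adjusted p = 0.0095), and the metal-binding metallothioneins MT1F and MT1G fell by 1.51 and by 1.33 (adjusted p = 0.021 each). DRAXIN, an axon guidance factor, fell by 1.25, SMR3B by 1.21, SULT1E1, an estrogen sulfotransferase, by 1.12, DACT2 by 0.96, MCAM, an adhesion molecule, by 0.93, PGF, a placental growth factor, by 0.90, and NSG1 by 0.88, with adjusted p between 0.021 and 0.045.

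In limma's fit without a block, 3 genes were higher and 0 lower in esiUSP9X, and 114 had an unadjusted p under 0.05. The third was SNORD35A, a small nucleolar RNA listed at 0 in esiGFP and at 289 and 285 FPKM in esiUSP9X, and USP9X itself was not called. The blocked fit called 9 higher and 20 lower of 12169, and 1321 had an unadjusted p under 0.05. With genes listed at 0 left out it called 115 in all, and 1437 of 12062 had an unadjusted p under 0.05. Both shares are over 0.05, so the few calls do not show that few genes changed. The count without a block was 1 without esiUSP9X 1 and 2 without esiUSP9X 2. The blocked count was 203 without esiGFP 1, 266 without esiGFP 2, 12 without esiFLI1 1, 16 without esiFLI1 2, 15 without esiUSP9X 1 and 14 without esiUSP9X 2.

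The EWS-FLI1 target lists were not called in esiUSP9X. The 37 activated targets had a median log2 change of 0.05 (replicates 0.10 and -0.00, camera adjusted p = 0.61), with -0.23 for the caveolin CAV1, which is among those with the highest FPKM. The 19 repressed targets had a median of 0.01 against a mean of -0.02 and an upward test (camera adjusted p = 0.96), with -0.11 for DKK1 and 0.03 for the matrix protein TNC. Limma called 0 members of either list without a block, also when adjusted over the list alone, and 0 in the blocked fit. Adjusted over the list alone, the blocked fit called 1 activated target higher, and 2 repressed targets higher and 2 lower. Of all 12169 genes, 114 had an unadjusted p under 0.05 in limma's fit without a block. That share is itself under 0.05, so these genes are not read as changed from that fit alone. USP9X, which the blocked fit called lower, is among them, so the share does not show them to be unchanged either.

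Of the 25 lists, 4 were called in esiUSP9X without a block and 5 in the blocked fit, with 0 members called by limma in the 4, and 0 lists were called with an estimated correlation. S phase genes were lower (35 genes, median -0.16, camera adjusted p = 4.3e-05; adjusted p = 0.65 with an estimated correlation), with PCNA at -0.38 and MCM7 at -0.06. Proteasome subunits were lower (31 genes, median -0.11, camera adjusted p = 0.0048; adjusted p = 0.65 with an estimated correlation), with PSMA7 at -0.23 and PSMB1 at -0.29. Cholesterol synthesis genes were higher (24 genes, median 0.10, camera adjusted p = 0.0013; adjusted p = 0.65 with an estimated correlation), with FDPS at 0.09 and IDI1 at 0.10. Histone genes were higher (11 genes, median 0.20, camera adjusted p = 0.0069; adjusted p = 0.98 with an estimated correlation), with HIST1H2BD at 0.23 and HIST1H2BK at 0.12. Adjusted over the list alone, 0 members of these 4 lists were called without a block, and 3 histone genes were called higher in the blocked fit. The 3 kept epithelial markers, with a median of 0.13, were called in the blocked fit (adjusted p = 0.029; adjusted p = 0.93 with an estimated correlation) and not without a block (0.15). There KRT8 rose and KRT18 was 0.13 and not called, and the call ended without esiGFP 1 (0.51), esiGFP 2 (0.44), esiUSP9X 1 (0.058) or esiUSP9X 2 (0.082) and with a GC correction (0.067), which without a block called the list (0.045), with 0.015 to 0.70 over all alternatives. All 4 calls ended without esiGFP 2 (S phase 0.22, proteasome 0.86, cholesterol 0.66, histones 0.43) or without esiUSP9X 1 (0.076, 0.16, 0.16 and 0.43), where the cholesterol median turned negative (-9.1e-04 and -0.030), and in the blocked fit without esiGFP 1 (0.072, 0.072, 0.072 and 0.51) or esiGFP 2 (0.44, 0.89, 0.50 and 0.10). Blocked calls of the proteasome and cholesterol lists also ended without esiUSP9X 2 (0.29 and 0.14), the proteasome call ended under quantile normalization (0.055) and the histone call with no filter (0.17). Adjusted p over all alternatives ran from 1.0e-06 to 0.65 for S phase, 2.5e-04 to 0.89 for the proteasome, 3.1e-05 to 0.66 for cholesterol and 2.3e-06 to 0.98 for histones.

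The comparison of esiUSP9X with esiFLI1 tests whether the effects of the knockdowns differ. The genes that esiFLI1 raised most were also far higher in esiFLI1 than in esiUSP9X. DKK1 was lower in esiUSP9X than in esiFLI1 by 6.67 on the log2 scale (a change of -6.67, SE 0.32, adjusted p = 0.0052), and IGFBP5 (-5.70), POSTN (-5.70), MGP (-4.39), NT5E (-4.33), L1CAM (-4.27), CRYAB (-4.03), TGFB2 (-3.99), LOX (-3.93) and the related crosslinking enzyme LOXL2 (-3.89) were lower too. Higher in esiUSP9X were PPP1R1A (2.37), ETV4 (2.33), ASNS (1.95), FEZF1 (1.93), CCK (1.83), AMER2, a Wnt pathway regulator (1.83), SCNN1G, a sodium channel subunit (1.80), CLSTN2, a synaptic protein (1.77), and MYOM2, a sarcomere protein (1.76), with adjusted p of at most 0.034. FN1 also passed the test, but it was listed at 0 in both esiFLI1 libraries, so it is not read as lower there. In the blocked fit NR0B1 (2.59), ATF5 (2.37), TRIB3 (2.08), LBH (1.95) and VMO1 (1.92) were also higher in esiUSP9X.

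Between these knockdowns the EWS-FLI1 target lists differed. Of the 37 activated targets, 7 were higher and 0 lower in esiUSP9X than in esiFLI1 (18 and 0 adjusted over the list alone, 30 and 2 blocked; median 0.73, camera adjusted p = 1.1e-13; adjusted p = 0.073 with an estimated correlation). Of the 19 repressed targets, 0 were higher and 12 lower (0 and 14 adjusted over the list alone, 1 and 15 blocked; median -1.50, camera adjusted p = 9.3e-14; adjusted p = 0.073 with an estimated correlation). Of the 25 lists, 14 were called with or without a block and 0 with an estimated correlation. Limma called 51 genes higher and 324 lower without a block (1931 at an unadjusted p under 0.05), and 2453 higher and 2543 lower in the blocked fit. The count without a block was 81 without esiGFP 1, 91 without esiGFP 2, 2 without esiFLI1 1, 4 without esiFLI1 2, 0 without esiUSP9X 1 and 4 without esiUSP9X 2. The blocked count was 2574 without esiFLI1 2, 2889 without esiUSP9X 1 and 2955 without esiUSP9X 2.

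Whether USP9X loss moves the genes that FLI1 loss moves was asked with the overlap of calls and with the correlation of fold changes. Without a block, 1 gene, EEF1A1, was called in the same direction in both knockdowns, where independent lists would share 0.0774 and unchanged groups against the same controls shared 0.01 on average. The EEF1A1 call rests on values listed at 0 in both esiGFP libraries, so it is not read as a shared effect. The blocked fit shared 4 higher genes (EEF1A1, KRT8, RPN1 and ABHD14A-ACY1) and 5 lower ones, and 8 genes moved in opposite directions. The lower ones were MT1G, PALM3, SULT1E1, ABHD3 and a small RNA, where PALM3 fell by 1.35 in esiFLI1 and by 0.83 in esiUSP9X, and ABHD3 by 1.17 and by 0.71. Independent lists would share 1.85 higher and 4.31 lower genes, and simulated unchanged groups shared 0.89 and 1.31 on average, with at most 8 in all. The count without a block was 2 without esiGFP 1. The blocked count was 116 without esiGFP 1, 153 without esiGFP 2, 4 without esiFLI1 1 and 5 without esiUSP9X 2. With genes listed at 0 left out, 0 genes were shared without a block (limma), and 47 with it, beside 32 genes in opposite directions. There independent lists would share 9.92 higher and 16.7 lower genes, and simulated unchanged groups shared 0.33 and 0.35 on average, with at most 3 in all. Neither knockdown had an effect in the simulations, so few genes were called there and few could be shared. An effect of esiFLI1 alone with shared controls was not simulated, so a shared effect is not read from these counts.

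Across the 12169 kept genes, which are not independent replicates, the fold changes of the knockdowns had a Pearson r of 0.226 and a Spearman rho of 0.172. Unchanged groups against the same controls had a simulated r of 0.503, which follows from the shared controls alone. The fold changes spread more in esiFLI1 (SD 0.623) than in esiUSP9X (SD 0.316), which lowers the observed r. An r under 0.503 therefore says nothing on a shared effect. The covariance was 0.0444 against 0.0132 on average in those simulations (at most 0.0194), a difference of 0.0312. With genes listed at 0 left out it was 0.0177 against 0.00745 on average (at most 0.00795), a difference of 0.0103. Within replicates, r was 0.196 in replicate 1 and 0.375 in replicate 2. It was 0.454 without esiGFP 1, 0.459 without esiGFP 2 and 0.0606 without esiUSP9X 2. When both libraries of each knockdown were set against a different control library, r was -0.175 and -0.152. There the difference between replicates, which the groups share, enters the fold changes with opposite signs. That lowers r, so its negative sign is not read as a reversal. With single libraries against the control of their own replicate number, added after the data were seen, r was 0.0717 and -0.0249. Of the genes that passed the blocked test in esiFLI1 with at least a 2-fold change and were above 0 in all libraries, the 608 higher ones had a median of 0.020 in esiUSP9X (replicates -0.029 and 0.077, with 54.9% higher) and the 179 lower ones -0.093 (replicates -0.070 and -0.10, with 68.2% lower). The medians that shared controls alone would give were not computed.

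**Figure D3:**
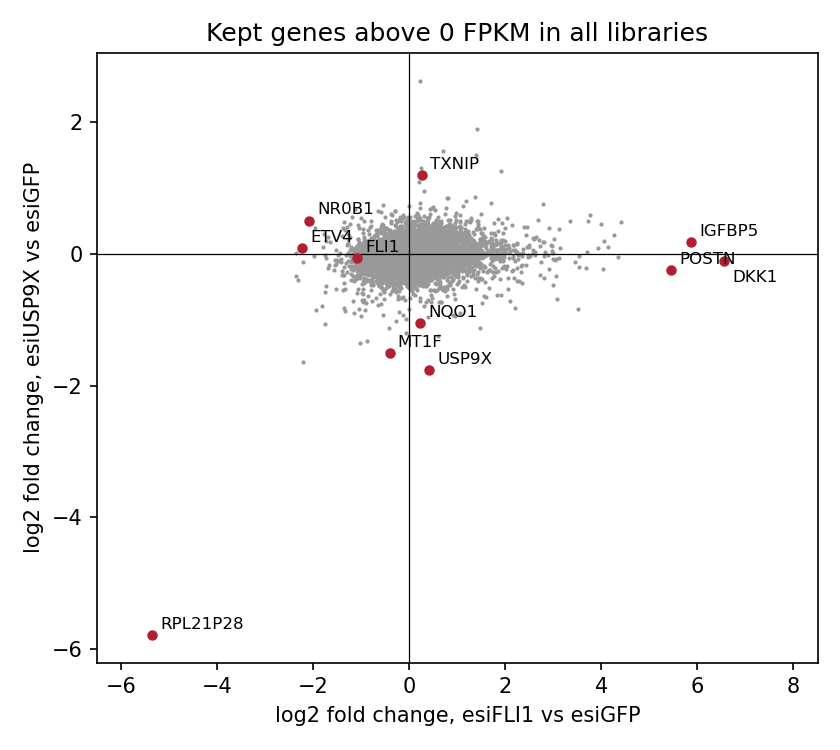
Log2 fold change in esiUSP9X against esiGFP (y axis) and in esiFLI1 against esiGFP (x axis) for the kept genes above 0 FPKM in all libraries, a point per gene, with genes of the text in red. DKK1, at 6.56 in esiFLI1, lay at -0.11 in esiUSP9X, and RPL21P28 lay apart at the lower left.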

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

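Depth limits every value here, since read counts are unknown and the floor of a 0 value cannot be given. With 2 libraries per group, the fit without a block rests on 3 residual degrees of freedom, and its counts in both comparisons with esiFLI1 moved by more than 1.5 times when any library was left out. A left-out library leaves its group with a lone sample, which is assumed to vary like the other groups. With the block such a fit has fewer residual degrees of freedom than the 2 of the full blocked fit. Its p-values and counts then rest mostly on the prior spread, and its smallest p-values are not read as stronger evidence. The replicate block, fixed in advance, removes by its construction the part of the spread that same-numbered libraries share. The settings without genes listed at 0 and with a GC correction, and their combinations with the block, were added after the data were seen, as were median scaling and left-out libraries with the block. Added then too were single libraries of each knockdown against the control of their own, different replicate numbers, while both libraries of each knockdown against a different control library was fixed in advance. For the other changes below the cause was not tested, except where fewer genes or samples enter by construction (a filter, genes left out, only the 2 groups compared, a stricter threshold).

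Of 342 genes changed in esiFLI1, the block gave 5125, the block without genes listed at 0 gave 5530, the block with median scaling 5207, the GC correction 2758 and the GC correction with the block 6287. No filter gave 558, a filter of 5 FPKM 139, only the 2 groups compared 56, and an adjusted p under 0.01 also 56. With a library left out, in either fit, the count ran from 1 to 4771. In place of 3 genes in esiUSP9X, limma called 0 without genes listed at 0 (114 of all kept genes had an unadjusted p under 0.05), 29 with the block, 115 with the block and no genes at 0, 20 with the block and GC correction, and 29 with the block and median scaling, and from 1 to 266 with a library left out. In place of 375 genes between esiUSP9X and esiFLI1, a filter of 5 FPKM gave 154, the block 4996, the block without genes listed at 0 5501, the GC correction 2746, this with the block 6270, the block with median scaling 5118, only the 2 groups 69 and an adjusted p under 0.01 58, and a left-out library 0 to 5370. The shared call, 1 gene, became 0 without genes listed at 0 in limma's fit, 9 with the block, 47 with the block and no genes at 0, 5 with the block and GC correction, 9 with the block and median scaling, and 1 to 153 with a library left out. Counts under other pseudocounts, median scaling, quantile normalization, both other eBayes settings and without small RNA symbols stayed within 1.5 times. Higher calls made up 90.6% in esiFLI1 with median scaling and 86.0% with quantile normalization. The GC correction gave 1445 higher and 1313 lower genes in esiFLI1 in place of 314 and 28, and 1315 higher and 1431 lower between esiUSP9X and esiFLI1 in place of 51 and 324.

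The correlation of fold changes, 0.226, was -0.175 and -0.152 when each knockdown was set against a different control library with both of its own libraries, 0.0717 and -0.0249 for single libraries against the control of their own replicate number, and from 0.0606 (without esiUSP9X 2) to 0.459 (without esiGFP 2) with a library left out. With both libraries per knockdown, the difference between replicates enters with opposite signs, which lowers r.

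With the block, FLI1 in esiFLI1 was -1.09 (adjusted p = 4.4e-04), USP9X in esiUSP9X -1.77 (4.5e-04), USP9X in esiFLI1 0.41 (0.013) and EWSR1 in esiFLI1 -0.31 (0.048). With the block and no genes at 0 they were -1.09 (4.4e-06), -1.77 (1.2e-06), 0.41 (0.0061) and -0.31 (0.031). With the block and median scaling they were -1.11 (3.3e-04), -1.77 (5.7e-04), 0.40 (0.016) and -0.33 (0.030), and with the block and GC correction -1.18 (0.0013), -1.78 (9.1e-04), 0.33 (0.0068) and -0.40 (0.023). The GC correction without the block also called FLI1 in esiFLI1 (-1.18, 0.0079) and USP9X in esiUSP9X (-1.78, 0.011). Over all alternatives, adjusted p ran from 5.1e-11 to 0.50 for FLI1 in esiFLI1, 1.4e-20 to 1 for USP9X in esiUSP9X, 0.0061 to 0.88 for USP9X in esiFLI1, 0.023 to 0.78 for EWSR1 in esiFLI1 and 0.75 to 1 for FLI1 in esiUSP9X. Without single libraries, FLI1 in esiFLI1 ran from -1.38 to -0.81, USP9X in esiUSP9X from -1.95 to -1.59, USP9X in esiFLI1 from 0.16 to 0.67, EWSR1 in esiFLI1 from -0.44 to -0.18, and FLI1 in esiUSP9X, never called, from -0.36 to 0.22.

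These results, uncalled without a block except cholesterol synthesis in esiUSP9X, changed sign or became 0. In esiFLI1, quantile normalization gave FDPS 0.015, IDI1 0.055, RPL7 0, RPS27 0.081 and the G2 and mitosis list 0.12, and in esiUSP9X EWSR1 0.048. The GC correction, alone or with the block, gave the ETS list -0.039 in esiFLI1, and the collagen chains 0.0095 in esiUSP9X. Without a filter the neural list was 0.026, and with a filter of 5 FPKM the Wnt list was 0.54, both in esiFLI1. With a library left out, in esiFLI1, RPLP2 ran from -1.52 to 0.36, FDPS from -0.41 to 0.15, IDI1 from -0.51 to 0.28, RPL7 from -0.47 to 0.17, RPS27 from -0.43 to 0.019 and MT1G from -1.91 to 0.14. Of the esiFLI1 lists, apoptosis ran from -0.13 to 0.13, deubiquitinases from -0.11 to 0.024, ETS factors from -0.14 to 0.14, G2 and mitosis from -0.16 to 0.12, p53 targets from -0.14 to 0.10 and metallothioneins from -1.29 to 0.78. In esiUSP9X, FDPS ran from -0.19 to 0.37, IDI1 from -0.15 to 0.35, DKK1 from -0.63 to 0.42, TNC from -0.043 to 0.11, KRT18 from -0.12 to 0.38, HIST1H2BK from -0.051 to 0.29, MCM7 from -0.23 to 0.11, EWSR1 from -0.11 to 0.083 and MT1X from -2.27 to 0.24. Of the esiUSP9X lists, cholesterol synthesis ran from -0.030 to 0.34, activated targets from -0.046 to 0.13 and repressed targets from -0.13 to 0.18. The tRNA synthetases ran from -0.068 to 0.12 and collagen chains from -0.34 (without esiGFP 2) to 0.22 (without esiGFP 1). Those collagen values are without the block, and with it they were -0.17 and 0.060. In a further 17 uncalled list tests the direction of the test changed while the median kept its sign.

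Of 107 other gene results in esiFLI1, the block added 58 calls and ended 0, and the GC correction added 39 and ended 1. Only the 2 groups compared ended 28, a filter of 5 FPKM 6, quantile normalization 3, and each of the other settings at most 2. Leaving out a library without the block ended 42 (esiGFP 1), 44 (esiGFP 2), 37 (esiFLI1 1), 37 (esiFLI1 2), 28 (esiUSP9X 1) and 28 (esiUSP9X 2). Of 35 such results in esiUSP9X, the block added 19 calls and no setting in which the gene was kept ended any (0). Of 25 between esiUSP9X and esiFLI1, the block and the GC correction each added 5, only the 2 groups compared ended 9, and a left-out library ended 9 (either esiGFP), 17 (esiFLI1 1), 16 (esiFLI1 2) and 19 (either esiUSP9X). An estimated correlation ended all called lists that are reported here, 17 in esiFLI1 with the gene families, 5 in esiUSP9X and the 2 compared between the knockdowns. That setting also tests on the few residual degrees of freedom, so an ended call does not show that correlation between genes accounts for it. For the activated targets in esiFLI1 the estimated correlation was 0.0042, under the preset 0.01. In the other lists called there it was over the preset, from 0.025 (repressed targets) to 0.58 (histones), with 0.33 for ribosomal proteins. Camera p-values with the preset may therefore be too small for those lists.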

Other observations

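The tests on gene families, on GC content as the whole cause of the correlation, and on EWS-FLI1 activity in the esiUSP9X cells were chosen after results were seen.

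Collagen genes rose together in esiFLI1. Of 25 kept collagen chains, 9 rose and 0 fell without a block and 24 rose in the blocked fit, with a median log2 change of 1.56 (camera adjusted p = 3.6e-17; adjusted p = 0.14 with an estimated correlation, the highest of 1.7e-32 to 0.14 over all alternatives). COL11A1 rose by 3.71 (SE 0.14, 0.0649 to 12.9 FPKM, n = 2, adjusted p = 0.0033), COL12A1 by 2.45 and COL6A3 by 2.62, and COL1A1, the main chain of type I collagen, by 3.46 in the blocked fit (adjusted p = 5.6e-06). In esiUSP9X the collagen median was -0.056 (adjusted p = 0.66), and 0.0095 with a GC correction. Without a block, that median was -0.34 without esiGFP 2 and 0.22 without esiGFP 1, and camera with the preset correlation called the list in both settings. Its sign depended on the control library left out, so neither call is read as a change. With the block these medians were -0.17 and 0.060.

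Cytosolic tRNA synthetases, which load amino acids onto tRNA, fell in esiFLI1. Of 20 kept genes, 17 fell in the blocked fit and 0 were called by limma without a block (6 lower adjusted over the list alone), with a median of -0.61 (camera adjusted p = 9.0e-08; adjusted p = 0.079 with an estimated correlation, the highest of 1.2e-09 to 0.079 over all alternatives). MARS fell by 1.11, YARS by 1.04, GARS by 1.03 and SARS by 0.93 in the blocked fit. Their median in esiUSP9X was 0.023 (adjusted p = 0.61; 0.048 without esiGFP 2, with 0.048 to 0.99 over all alternatives). Metallothioneins, small metal-binding proteins, were lower in esiUSP9X, where MT1F (-1.51), MT1G (-1.33), MT1X (-1.02) and MT2A (-0.93) fell in the blocked fit and MT1E was not called (blocked adjusted p = 0.17). The 5 genes had a median of -1.02 (camera adjusted p = 6.0e-04; adjusted p = 0.72 with an estimated correlation), a call that ended without esiGFP 1 (0.38) or esiUSP9X 2 (0.27), with 2.1e-16 to 0.72 over all alternatives. In esiFLI1 their median was -0.28 (adjusted p = 0.53; called in the blocked fit without esiFLI1 1, 0.044, with 0.044 to 0.79 over all alternatives), and near-identical copies make single metallothionein values uncertain.

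Replicate 2 differed from replicate 1 in a like way in all 3 groups. The difference followed the GC content of the transcript, with a Spearman rho of -0.822 in esiGFP, -0.854 in esiFLI1 and -0.806 in esiUSP9X across 11470 genes, so GC-dependent yield during library preparation or sequencing is a candidate explanation. Transcript length went with it more weakly (0.239, 0.257 and 0.251), which neither excludes length nor makes it sufficient. Against esiGFP, fold changes followed GC with a rho of -0.151 in esiFLI1 and -0.162 in esiUSP9X, far less than the replicates did, and length with a rho of 0.214 and 0.165. The labels give no batch or day, and no biological explanation was tested.

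Genes with abundant transcripts were listed at 0 in whole groups, EEF1A1 in esiGFP, and FN1 in esiGFP and esiFLI1. By FPKM times transcript length, EEF1A1 ranked 2 and FN1 ranked 4 among 11470 genes where they had values, so loci with too many fragments for the authors' quantification may have been given no value. The other 8 of the 10 highest, such as GAPDH and HSP90AA1, were listed at 0 in no library, so rank alone is not sufficient. The settings of the quantification are not given in the sources used here. A biological loss of either transcript in the control cells was not tested.

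The fold changes of the knockdowns correlated (r = 0.226). Their covariance, 0.0444, exceeded the highest of 100 simulations of unchanged groups with shared controls, 0.0194. With genes listed at 0 left out it was 0.0177 against at most 0.00795. The simulated r (0.503) follows from shared controls alone, and the wider spread in esiFLI1 lowers the observed r, so these r values are not compared. Single libraries against different controls gave r of 0.0717 and -0.0249. Only the second meets the bound set for shared control libraries as the cause (0.05). The covariance lay above the simulations, but 1 combination without shared controls had no positive r. Shared controls therefore cannot be told apart from a shared effect. Both libraries of each knockdown against a different control gave -0.175 and -0.152, but there the difference between replicates enters with opposite signs. That lowers r, so these values do not decide the question. With the shared controls, a GC correction, which keeps only genes with a known GC content, left r at 0.218. Shared controls alone can keep r positive, so this value does not decide on GC content as the whole cause. Against different controls, with genes listed at 0 left out, r was 0.162 and -0.0300 before that correction and 0.187 and -0.0915 after it, so 1 combination kept its r, the other had no positive r to remove, and a part played by GC content stays open. Loss of EWS-FLI1 activity in the esiUSP9X cells would give a positive slope over the EWS-FLI1 targets, and with different controls the slope across 56 of them above 0 in all libraries was 0.0304 and -0.0471, which argues against a loss of the size that would give 0.1 or more.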
